A study of Caenorhabditis elegans with 2 samples.

How the data were processed

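ChIP-seq of tagged NHR-237 was deposited for 2 samples, which the labels call biological replicates 1 and 2 of whole L4 larvae, fragmented by sonication. They formed 1 group. For each replicate and for both together, the authors deposited a list of peaks and background regions made as input for the irreproducible discovery rate (IDR) procedure, and they deposited the regions that passed it as the optimal IDR thresholded peaks. Per the text file deposited with each sample, the IDR peaks were derived from the pooled list and both replicates' lists. The lists exist for 2 genome builds, ce11 and ce10, and each was analysed in its own coordinates with no conversion. The antibody field of the labels names only NHR-237. The aligner, the peak caller, the IDR threshold and the filters are not given in the sources used here.

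The deposited signal of a region is the authors' own value for it, in the signal column of the narrowPeak format. Its scale is not given in the sources used here and differs between lists, so it was used only to rank and describe regions within a list or, between replicates, as log10 values in a correlation. The deposited −log10 q values take few distinct values at the top of each list (413 of the 26787 pooled regions share the maximum of 2.07), so they were not used for ranking. The p column holds no values. Each replicate's list ends at exactly 30000 regions, so it includes background by design, and presence in it alone says little. In the pooled list 340 bp was both the median and the maximum width. The narrower regions numbered 23, so positions were taken from the summit column.

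The lists hold no read counts, so the depth of the samples is unknown, and no interval here covers sequencing error. Intervals are exact (Clopper-Pearson) 95% binomial intervals over peaks and cover counting error only. For a gene list with a count of 0, the limit given is instead approximate, 3 counts out of the number of targets. Tests ran over peaks or genes, not over replicates, so their p-values do not measure the spread between worms, and neighbouring peaks are not independent. The labels name a possible control experiment, and the text files deposited with the samples list control-normalized signal tracks. Neither these tracks nor an untagged strain was used here. Whether a control entered the deposited peak calls is not given in the sources used here, and whether some peaks give signal in any ChIP was not tested.

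The deposited IDR list holds 237 peaks on ce11 and 238 on ce10. Except for the ce10 alternatives, computations were on ce11, with the WBcel235 reference sequence and the Ensembl release 115 annotation, whose chromosome lengths hold all regions of the lists. The background for tests over peaks was the 26503 pooled regions that overlap no IDR peak by 1 bp or more, or those of the same chromosomes. Gene lists were tested against the 10814 genes next to any pooled region, and autosomal and X peaks were also compared with each other. A promoter was the stretch from 1000 bp upstream to 200 bp downstream of the 5′ end of any protein-coding transcript. Other summits were placed, in this order, in 5′ UTR, coding exon, 3′ UTR, intron or between genes. The target of a peak was the protein-coding gene with the 5′ end nearest to the summit, within 2000 bp. In worms trans-splicing removes the start of many transcripts, so annotated 5′ ends can lie downstream of the true start. Fisher's exact test was used for promoters, 31 gene lists, 5 classes of RNA genes (summit within 500 bp), 14 motifs and 2080 6-mers in 201 bp windows. An exact binomial test was used for the 7 chromosomes. All were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Of 268 gene symbols listed by name, 264 were found in the annotation, and other members were found by name patterns. Replicate signal was compared by Spearman's rho and Pearson's r with 100000 permutations, taking the strongest overlapping region per peak, so neighbouring peaks can share a region. Chance recovery came from 1000 circular shifts of the nuclear peaks.

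The samples, tests, lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. The rule named the targets of the 25 IDR peaks of the highest signal, up to 4 members with the highest signal of each list that passed, nhr-237 and unc-119, and the 2 strongest pooled regions outside the IDR set. Other members of lists and RNA classes are named because their counts are small, and were chosen after their values were seen. Alternatives fixed at that stage were the ce10 lists, the peaks at or above the median signal, 50% reciprocal overlap or summits within 100 bp as the meaning of overlap, and the top 1000 regions of a replicate. Further ones were the genome every 200 bp (or all protein-coding genes) as background, other windows and distances, flanks 500 bp from the summit as motif background, and leaving out each replicate, where the 237 strongest regions of the other replicate's list took the place of the IDR peaks. Alternatives added after seeing the data were nuclear chromosomes alone, autosomes alone for the shares of chromosomes, a correlation in which each pair of replicate regions counted once, and an exact test within 5-point bins of GC content on nuclear chromosomes. This GC test was changed after its results had been seen. It was first run as Fisher's exact test against 20 background regions drawn per peak from the same GC bin, with replacement, in 2 versions that differed in the random seed. The calls for snoRNA, miRNA and TTTCAG differed between these versions, and draws with replacement count regions more than once, so the exact test on all background regions replaced them. The drawn form was then repeated 100 times to count how often each call is made. The random seed of all computations was also changed once after results had been seen.

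The statistics were tested on simulated data. In 100 random draws of 237 background regions, promoters passed in 5 draws, X in 6, any gene list in 1 and any motif in 3. With 10 regions at ribosomal protein genes planted, the list passed in 20 of 20 draws. A raised promoter share, a raised X share and a motif planted in 20 windows were likewise each found in 20 of 20. In 5 draws with nothing planted, at most 1 of 2080 6-mers passed, and 1 planted in 30 windows passed in 5 of 5. The permutation test of a correlation passed in 7 of 100 draws of unrelated values and in 20 of 20 with a true correlation of 0.5. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.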

Results

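NHR-237, a member of the nuclear hormone receptor family of transcription factors, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L4 larvae of Caenorhabditis elegans. The worms came from the transgenic strain OP228, in which NHR-237 carries GFP and FLAG at its C terminus, and the labels give a pool of both sexes. There was 1 group with 2 biological replicates and no second condition. The comparisons therefore set the authors' final peaks against weaker regions and background of the same libraries. Each replicate's list held 30000 regions, and the list from both replicates together (the pooled list) held 26787. The authors kept 0.885% of these after testing irreproducibility between replicates (the IDR peaks), 147 on autosomes, 66 on X and 24 on mitochondrial DNA. The lists give no read counts, so sequencing depth is unknown. The pooled list includes background by design, and its median −log10 q was 0.0875, against 2.07 for the IDR peaks. The tests below thus come close to setting peaks against the genome. Whether peaks of any ChIP would show the same differences was not tested.

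The IDR peaks came from every chromosome and from mitochondrial DNA, and their signal, the authors' own value per peak, ran from 31 to 369 with a median of 41.7. They were the pooled regions of the highest signal with no gap in rank, and all shared a −log10 q of 2.07. The first 2 regions outside the set lay 338 bp upstream of rpl-23 (III, 5706295 to 5706634), a ribosomal protein gene, and 196 bp upstream of uggt-1 (X, 7501008 to 7501347). Replicate 1 alone held every peak (100%, exact 95% interval 98.5 to 100%). Replicate 2 held 231 (97.5%, interval 94.6 to 99.1%). Nuclear peaks shifted at random along their chromosomes met the replicates' lists in 19.5% and 19.9% of cases on average over 1000 shifts. Among as many of the strongest regions of each replicate as there are IDR peaks, 185 of the peaks (78.1%) were found in replicate 1 and 149 (62.9%) in replicate 2. Of that top set of replicate 1, 115 regions (48.5%) overlapped the top set of replicate 2. Both lists went into the authors' selection, so this recovery is not an independent test.

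Signal in the replicates rose together across the 231 peaks found in both, with Spearman's rho of 0.502 and Pearson's r of log10 signal of 0.680. The relation was strongest for X peaks (rho 0.629, r 0.721, 65 peaks), lower for autosomal peaks (rho 0.214, r 0.372, 144 peaks) and near 0 for mitochondrial peaks (rho 0.0193, r 0.0641, 22 peaks). Neighbouring peaks can overlap the same region of a replicate: the 22 mitochondrial peaks rested on 14 regions of replicate 1 and 15 of replicate 2. With each pair of regions counted once, which was done after the correlations were seen, rho was 0.464 over 223 pairs, 0.608 over 63 pairs on X and 0.0339 over 16 mitochondrial pairs (adjusted permutation p = 2e-05, 2e-05 and 0.9). Autosomal peaks shared no region. Permutation tests, two-sided and adjusted over the 4 sets of peaks, gave p = 2e-05 for rho over all peaks (raw p = 1e-05, the smallest that 100000 resamples can give). The adjusted p of rho was 2e-05 for X, 0.013 for autosomes (raw 0.0096) and 0.93 for mitochondrial DNA. Differences between these sets were not tested. Without the 2 peaks of a set farthest from its median in replicate 1, r was 0.673 over all peaks, 0.286 for autosomes and 0.681 for X. Over the 209 nuclear peaks found in both lists, a setting chosen after the results were seen, rho was 0.362. The IDR peaks were exactly the pooled regions of the highest signal, from a selection that used the same replicates. Single peaks can thus be weak in 1 replicate, with ranks down to 26606 in replicate 2. These correlations and their p-values are not an independent test of reproducibility. Peaks are not independent replicates either, and over the 7950 pooled regions found in both lists, without that selection, rho was 0.178.

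**Figure D1:**
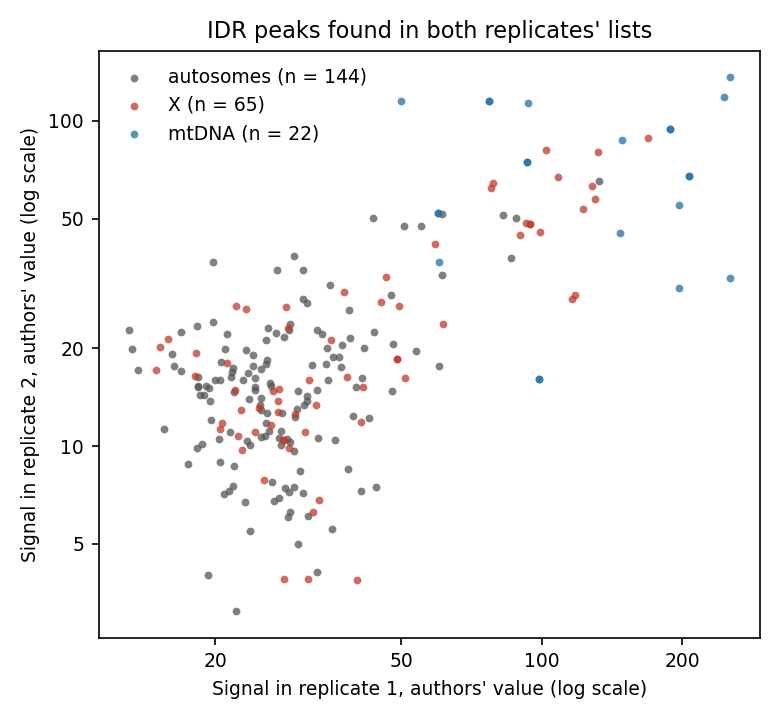
Signal of each IDR peak in replicate 1 (x axis) against replicate 2 (y axis), in the authors' units on log axes, for 144 autosomal, 65 X and 22 mitochondrial peaks found in both lists, where peaks that share a region of both replicates coincide. X peaks of high signal in 1 replicate tended to be high in the other (rho 0.629), while autosomal peaks formed a cloud (rho 0.214). There were exceptions on X, such as the peak nearest to ZC53.1, with rank 67 in replicate 1 and 18862 in replicate 2.

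X and mitochondrial DNA held more IDR peaks than their share of the other pooled regions, and chromosome V held fewer. X carried 66 peaks, 27.8% (exact interval 22.2 to 34%), against 17.2% of the 26503 pooled regions that overlap no IDR peak, a ratio of 1.62. Mitochondrial DNA, a molecule of 13794 bp, carried 24 peaks (10.1%), and 48.0% of its length lay under a peak. Only 2 of the other pooled regions were mitochondrial (0.00755%). Some of the 24 peaks overlap each other, so the p given below for mitochondrial DNA does not rest on independent peaks. Its test also treats the comparison share as known, though that share rests on only these 2 other regions. Chromosome V carried 20 peaks (8.44% against 18.9%) and chromosome II 23 (9.70% against 15.4%). In exact binomial tests, two-sided and adjusted over 7 chromosomes, p was 0.000106 for X (raw 4.55e-05), 3.82e-66 for mitochondrial DNA (raw 5.46e-67), 3.29e-05 for V (raw 9.41e-06) and 0.0257 for II (raw 0.0147). Chromosomes I (39 peaks, adjusted p = 0.842), III (36 peaks, adjusted p = 0.929) and IV (29 peaks, 12.2% against 17.1%, adjusted p = 0.0659) did not pass the exact test. IV passed with a lower share among peaks at or above the median signal (6.72%, adjusted exact p = 0.00196) and against the whole genome (adjusted exact p = 0.0487). Among the 213 nuclear peaks the X share was 31% (exact binomial p = 1.03e-06). In the top set of replicate 2 alone it was 22.4% against 17.3%, and neither X nor V passed the exact test (adjusted p = 0.0831 for both), nor did II (12.2% against 15.3%, adjusted p = 0.29). Shares sum to the whole, so more peaks on X and mitochondrial DNA lower every autosome: among autosomal peaks alone V stayed lower (13.6% against 22.8%, adjusted exact p = 0.0381) and II did not pass (15.6% against 18.6%, adjusted exact p = 0.497).

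The 25 peaks of the highest signal comprised 10 on mitochondrial DNA, 13 on X and 2 on autosomes. The mitochondrial peaks had as targets, the genes with the nearest 5′ end, ATP6 (signal 369), CYTB (331), COX3 (287), COX2 (236.6), ND1 (222), ND5 (213), ND3 (195) and ND4 (171), which encode subunits of the respiratory chain and ATP synthase. Their other targets were the mitochondrial genes WBGene00010964 (signal 148) and WBGene00010961 (signal 140). The 2 autosomal peaks lay at promoters. One was 257 bp upstream of rpl-3 (III, 3867477 to 3867690, signal 200), which encodes a protein of the large ribosomal subunit, and the other 161 bp upstream of cdc-48.1 (II, 10563479 to 10563676, signal 139), which encodes an AAA ATPase that unfolds ubiquitinated proteins. The strongest X peak (X, 11094048 to 11094351, signal 252) was intergenic and 3991 bp from the nearest 5′ end, that of W02H3.3. Of the 13 X peaks, 6 had no protein-coding 5′ end within 2000 bp. The other 7 had as targets F20B6.9 (signal 184), nspc-17 (176), T27A8.7 (173), F19H6.5 (142), F55G7.5 (141), the insulin-like peptide gene ins-39 (139) and the F-box gene fbxb-58 (136).

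**Figure D2:**
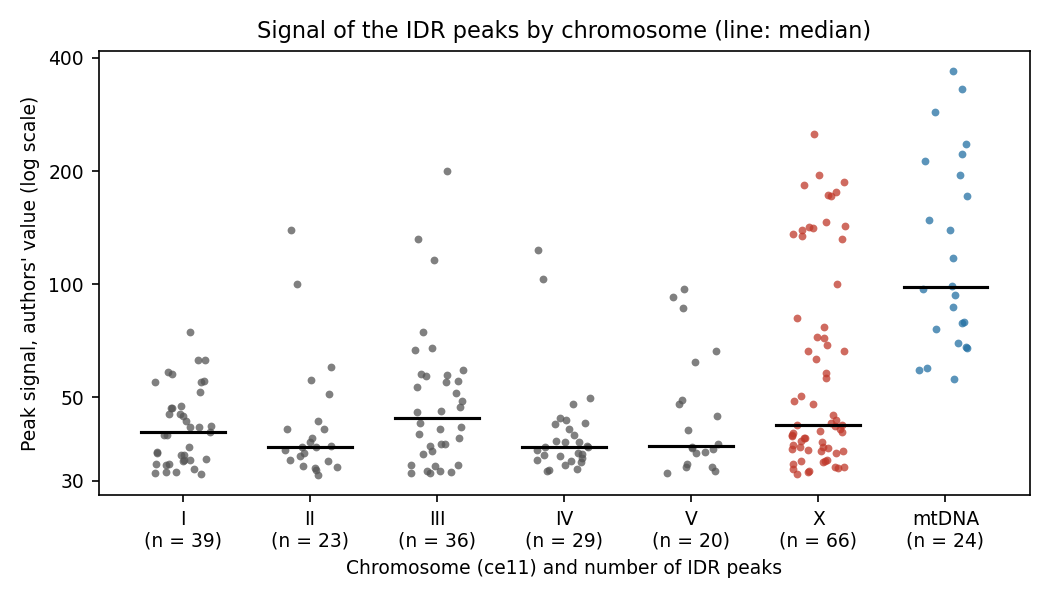
Signal of the IDR peaks (points, authors' value, log axis) by chromosome, with the median as a line. Mitochondrial peaks had the highest median (98), and 13 of the 25 strongest peaks lay on X.

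Autosomal IDR peaks lay mostly at promoters of protein-coding genes, and X peaks did so less often. Of all summits, 139 (58.6%, exact interval 52.1 to 65.0%) fell from 1000 bp upstream to 200 bp downstream of a transcript's 5′ end, against 29.9% of the other pooled regions. On autosomes this was 95 of 147 (64.6%, interval 56.3 to 72.3%) against 30.9%, and on X 25 of 66 (37.9%, interval 26.2 to 50.7%) against 25.3%. X peaks lay between genes in 45.5% of cases, outside any promoter window, where autosomal peaks did in 17.7%. The distance from a summit to the nearest 5′ end had a median of 453 bp for autosomal peaks, 1204 bp for X peaks and 1208 bp for the other pooled regions. Coding exons held 3.38% of peaks and 15.1% of the other regions. Adjusted over the 4 sets of chromosomes, Fisher's exact test, two-sided, gave p = 3.34e-19 for all peaks (raw 8.36e-20, odds ratio 3.32), 1.33e-16 for autosomes (raw 6.66e-17) and 0.0422 for X (raw 0.0317). The 24 mitochondrial peaks, on a molecule packed with genes, gave an adjusted exact p of 0.415. The autosomal and X shares differed from each other (Fisher's exact p = 0.000331).

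The promoter share of autosomal regions and the share of regions on X were lower further down the pooled list. The promoter share of autosomal regions was 48.1% at ranks 238 to 500 and 29.3% at ranks 10001 to 26787. The X share was 19.8% at ranks 238 to 500 and 17% in the last ranks. For X regions the promoter share did not fall steadily, with 26.9% at ranks 238 to 500, 37.8% at ranks 501 to 1000 and 23.3% in the last ranks.

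**Figure D3:**
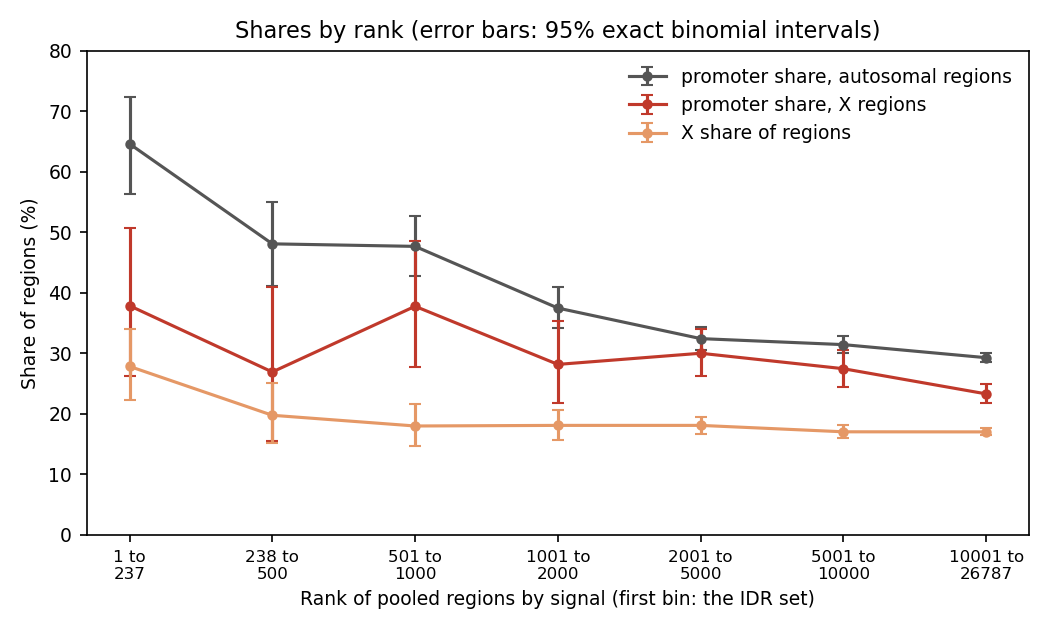
Share of pooled regions (y axis, percent) at promoters, for autosomes and for X, and share of regions on X, by rank of signal (x axis); error bars are exact 95% binomial intervals. The autosomal promoter share fell from 64.6% in the IDR set to 29.3% in the weakest regions, and the X share from 27.8% to 17%.

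Among genes next to IDR peaks, ribosomal protein genes and nuclear genes of the mitochondrial respiratory chain were more frequent than among genes next to any pooled region, and chemoreceptor genes less frequent. The peaks had 172 target genes (nearest 5′ end within 2000 bp), and the background was the 10814 genes next to a pooled region. Of 54 ribosomal protein genes in the background, 9 were targets (5.23% of targets against 0.423% of the rest, odds ratio 13). The strongest were rpl-3 (signal 200), rpl-35 (116, III), rpl-15 (103, IV) and rps-1 (41.3, III), and all 9 summits lay 32 to 454 bp upstream of the 5′ end. Of 29 respiratory chain genes, 4 were targets (odds ratio 10.1): the cytochrome c oxidase subunit genes cox-5B (signal 74.4) and cox-5A (57.1), the ATP synthase subunit gene atp-1 (35.8), and the cytochrome c gene cyc-2.1 (35.0). None of 546 chemoreceptor genes, which encode receptors of sensory neurons, was a target, where 5.13% of the rest were chemoreceptors. A count of 0 allows a share of up to about 1.74%, by an approximate limit of 3 counts out of 172. The chemoreceptor result is not separated here from the differences in chromosome, promoter share and GC content between peaks and other regions. Adjusted over 31 lists, Fisher's exact test, two-sided, gave p = 4.71e-06 for ribosomal proteins (raw 1.52e-07), 0.0111 for the respiratory chain (raw 0.00108) and 0.00431 for chemoreceptors (raw 0.000278). Among the peaks at or above the median signal, with 81 targets, none of the 3 lists passed the exact test (adjusted p = 0.0789, 0.153 and 0.219), with odds ratios of 8.06 for ribosomal proteins and 10.04 for the respiratory chain and 0 chemoreceptor targets. In the top set of replicate 2 alone, 2 chemoreceptor genes were targets (adjusted p = 0.132 in the exact test).

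The other 28 lists did not pass the adjusted test. Heat shock proteins (hsp-3, hsp-1), insulin-like peptides (ins-39, ins-13) and histones (his-37, his-68) had 2 targets each, with raw exact p of 0.0231, 0.0231 and 0.0292 and adjusted p of 0.143, 0.143 and 0.151. When every gene within 2000 bp counted as a target, these 3 lists and translation factors passed too (adjusted exact p between 0.0007 and 0.0411). That rule gave 284 targets in place of 172. Under it 1 peak can add several neighbouring genes, so the genes in that test are not independent. By the nearest-gene rule, translation factors had 2 targets (eef-1A.2, eef-1G, adjusted p = 0.282 in the exact test). Nuclear hormone receptors, the family of NHR-237 itself, had 4 targets of 161 genes (nhr-3, nhr-14, nhr-1 and daf-12, all on X; odds ratio 1.59, exact p = 0.328, adjusted 1). Cuticle collagens had 2 targets (col-94, col-3), and F-box proteins, neuropeptides, vacuolar ATPase and proteasome genes 1 each (fbxb-58, nlp-40, vha-15, rpn-3). No target was found among markers of intestine, hypodermis and seam, body wall muscle, pharynx, neurons or germline, nor among genes of the molting cycle, major sperm proteins or homeobox ceh genes. The same held for lipid metabolism, cytochrome P450 enzymes, UDP-glucuronosyltransferases, glutathione S-transferases, short-chain dehydrogenases and ABC transporters. It also held for C-type lectins, lysozymes and antimicrobial peptides, and proteases of the gut lumen and lysosome. With 172 targets, a count of 0 allows up to about 1.74% for each of these, by an approximate limit of 3 counts. Among the other background genes these lists made up only 0.113% (pharynx markers) to 0.911% (C-type lectins) each. These shares lie below that limit, so the counts of 0 do not show that any of these lists is avoided.

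Genes of non-coding RNA lay near IDR peaks more often than near other pooled regions in all 5 classes tested, and for tRNA and rRNA mostly through mitochondrial DNA. tRNA genes were within 500 bp of 23 summits (9.70% against 1.09%), 17 of them mitochondrial, and rRNA genes near 6 (2.53% against 0.0113%), 6 of them mitochondrial. The 6 summits near snRNA genes (2.53% against 0.151%, odds ratio 17.2) included 3 at sls-2.1, sls-2.2 with sls-2.3, and sls-2.4, which encode spliced leader RNAs, and had signals of 36.8 to 63.0. snoRNA genes were near 7 summits (2.95% against 0.736%) and miRNA genes near 4 (1.69% against 0.291%). The miRNA genes were mir-52 (IV), the cluster of mir-54 and mir-55 (X), mir-1824 (I) and mir-5549 (III), and the genes named for these classes were chosen after their values were seen. Adjusted over the 5 classes, Fisher's exact test, two-sided, gave p = 4.08e-14 for tRNA (raw 8.16e-15), 9.35e-11 for rRNA (raw 3.74e-11), 5.28e-06 for snRNA (raw 3.17e-06), 0.0028 for snoRNA (raw 0.00224) and 0.00587 for miRNA (raw 0.00587). On nuclear chromosomes rRNA genes were near none of 213 peaks (adjusted exact p = 1). tRNA genes were near 6 of these 213 peaks (2.82% against 1.08%, odds ratio 2.65, adjusted exact p = 0.0382), where the odds ratio over all peaks was 9.78. Against nuclear regions of the same GC content only snRNA passed (adjusted exact p = 3.16e-05), with 0.0666 for snoRNA and for miRNA and 0.406 for tRNA. Among peaks at or above the median signal, snoRNA did not pass (adjusted exact p = 0.732) and no peak lay near a miRNA gene.

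IDR peaks were rich in GAGA repeats and CG-rich motifs, while the half-sites that nuclear receptors are known to bind showed no difference that passed the test. GAGAGA occurred in 37.6% of windows reaching 100 bp to either side of summits against 13.2% around the other pooled summits, CTGCGTC, a motif common at worm promoters, in 14.8% against 2.57%, and GCGCGC in 13.1% against 1.87%. The receptor half-site AGGTCA occurred in 6.75% (exact interval 3.91 to 10.7%) against 5.11%, its variant AAGTCA in 6.33% against 8.80% and the core GGTCA in 17.3% against 17.1%. TTTCAG, the splice acceptor sequence, was less frequent (17.7% against 35.4%), as was the GATA site TGATAA (10.5% against 16.7%). Fisher's exact test, two-sided and adjusted over 14 motifs, gave p = 8.52e-20 for GAGAGA (raw 6.09e-21), 1.03e-15 for CTGCGTC (raw 2.21e-16), 5.71e-16 for GCGCGC (raw 8.16e-17), 9.75e-09 for TTTCAG (raw 2.79e-09) and 0.0301 for TGATAA (raw 0.0107). For AGGTCA, AAGTCA and GGTCA the adjusted exact p was 0.368, 0.368 and 1 (raw 0.237, 0.205 and 0.931). The interval of AGGTCA allows up to 10.7%, so a higher share is not excluded. Among autosomal peaks it was at 8.16% against 4.94% (odds ratio 1.71, raw exact p = 0.0833, adjusted 0.167), and GGTCA in the top set of replicate 2 at 22.8% against 17.1% (odds ratio 1.43, adjusted exact p = 0.0563). Within GC bins on nuclear chromosomes, AGGTCA in IDR peaks was at 7.04% against 6.17% and GGTCA at 18.8% against 21.3% (adjusted exact p = 0.846 for both). The other 6 motifs, TATAAA, CACGTG, CAGGTG, TGTTTAC and the C/EBP-type and AP-1 sites, did not pass either (adjusted exact p between 0.189 and 1). Windows of IDR peaks had a mean GC content of 44.6% ± 7.42 (SD, 147 windows) on autosomes against 35.7% ± 7.56 (SD, 21939 windows) in other pooled regions. On nuclear chromosomes alone TATAAA was less frequent (12.2% against 21.6%, adjusted exact p = 0.00158), but not within bins of equal GC content (12.2% against 11.1%, adjusted exact p = 0.846). The TGATAA call was lost among peaks at or above the median signal, against peak flanks and within GC bins (adjusted exact p of 0.176, 0.188 and 0.882). In the first 2 settings, which have fewer windows, the odds ratio was 0.561 and 0.637 against 0.590 in the main test, while within GC bins the shares themselves came close (10.3% against 11.4%). In those bins GAGAGA was at 41.3% against 21.7% (adjusted exact p = 2.05e-09), CTGCGTC at 16.4% against 5.72% and GCGCGC at 14.6% against 4.73% (adjusted exact p = 9.95e-08 for both), smaller ratios than without GC bins.

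**Figure D4:**
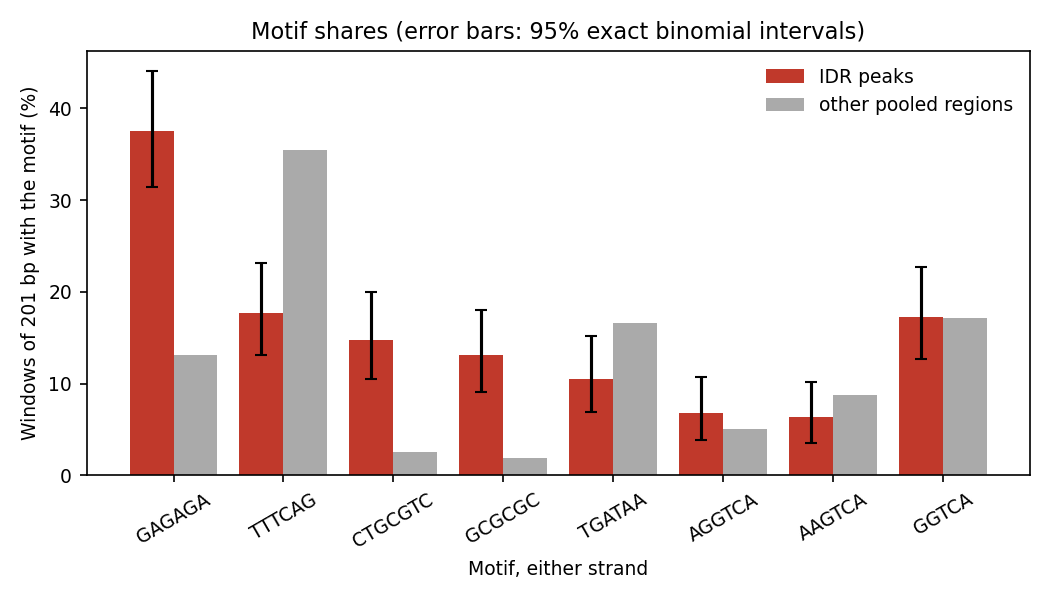
Share of windows, 100 bp to either side of a summit (y axis, percent) with a motif on either strand in IDR peaks (red, with exact 95% binomial intervals) and in the other pooled regions (grey), for the 5 motifs that passed the test and 3 nuclear receptor half-sites. GAGAGA reached 37.6% in IDR peaks, while AGGTCA was at 6.75% against 5.11%.

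Over all 2080 6-mers, with reverse complements joined, 439 passed Fisher's exact test after adjustment over them, 296 more frequent in IDR peaks and 143 less. The 6-mers were not tested within GC bins. Mean GC content was 44.6% against 35.7% in other regions on autosomes and 44.7% against 36.1% on X. How many of these calls follow from base composition is therefore not known. ACGCAG (25.7% against 5.18%, adjusted p = 3.38e-22 in the exact test, raw 2.74e-25) and AGAGAC (31.6% against 8.07%, adjusted p = 3.38e-22, raw 3.25e-25) led the list. A split by chromosome, made after the X excess had been seen, gave ACGCAG and GAGAGA at the top for autosomes. On X the first 4 were CCCTGC (30.3% against 2.54%), CCTGCG (27.3% against 2.39%), CTGCGC (28.8% against 3.16%) and CAGGGA (30.3% against 3.81%). Their adjusted exact p values lay between 1.53e-12 and 4.14e-10 over the 66 X peaks.

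Neither locus carried by the transgene held an IDR peak. The gene nhr-237 itself (V, 1625189 to 1626820) had 1 pooled region within a 40 kb window, against 10.7 expected from the length of the window. In that window replicate 1 had 1 region and replicate 2 had 2, against 12 expected for each. That pooled region ranked 8893 of 26787. The window around unc-119 (III, 10902641 to 10908935), a gene needed for movement and the rescue marker of the transgene, had 13 pooled regions against 10.7 expected, with a median signal percentile of 38.3. IDR status gave p = 1 at both loci in Fisher's exact test, and with 13 regions or fewer it had little power.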

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

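The settings on nuclear chromosomes or autosomes alone, with each pair of replicate regions once and within GC bins, and all settings of the X motif, were chosen only after the results were seen. The promoter share and the replicate correlation kept their direction and their side of the threshold under every alternative run for them. The promoter share ranged from 45.1% against 18.2% of other regions (500 bp upstream, 100 bp downstream) to 67.9% against 49.5% (2000 bp, 500 bp), so the lowest share had the largest ratio, and the correlation from 0.178 (all pooled regions) to 0.466 (ce10). The X share kept its direction and ranged from 22.4% to 29.1% in the single replicates, but its call was lost without replicate 1 (adjusted exact p = 0.0831); the cause was not tested. The peak count was 238 on ce10, and 204 peaks had 50% reciprocal overlap in both replicates. A count of peaks at or above the median signal is fixed by that choice, so it is not given as a result. Recovery in replicate 1 was 97% with 50% reciprocal overlap and 96.6% with summits within 100 bp. In replicate 2 these were 88.2% and 85.7%, and 83.1% among its top 1000 regions. Gene lists that passed numbered 0 among the peaks at or above the median signal, with fewer targets (81), and 7 when all genes within 2000 bp counted. RNA classes that passed numbered 3 among the stronger peaks and 1 within GC bins. The direction turned for miRNA among the stronger peaks (0%), where the cause was not tested, and for rRNA on nuclear chromosomes (0%) and within GC bins (0%), since all rRNA peaks were mitochondrial. In 100 repeats of the GC match with drawn regions, the form used first, snoRNA passed in 10, miRNA in 15 and TTTCAG in 66, so these 3 calls depend on the draw. In the exact form TTTCAG passed (18.3% against 26.2%, adjusted exact p = 0.0266) and the other 2 did not. In the same repeats snRNA, GAGAGA, CTGCGTC and GCGCGC passed in 100, and the other classes and motifs in 0. Windows of 20 kb and 80 kb held 0 and 11 pooled regions at nhr-237 and 8 and 26 at unc-119, against 5.34 and 21.4 expected from their length. Counts rise with the length of a window by construction. In the 40 kb windows the single replicates held 1 to 2 regions at nhr-237 and 11 to 15 at unc-119, against 12 expected. The cause of the low counts at nhr-237 was not tested. Motifs that did not pass also turned direction without passing after the turn. This held for TATAAA (24.4%), CACGTG (2.52%) and CAGGTG (4.2%) among the stronger peaks, and in the single replicates for CAGGTG (4.22% to 5.06%), CACGTG (3.38% to 4.22%) and TTGCGCAA (5.06% to 6.33%) in 1 replicate each. It held for TGASTCA (1.88%) and CAGGTG (4.69%) on nuclear chromosomes, and for GGTCA (18.8%), TATAAA (12.2%), TTGCGCAA (4.69%) and CAGGTG (4.69%) within GC bins. Windows of 50 bp to either side turned AGGTCA (2.11%) and CAGGTG (2.11%). Windows of 200 bp to either side turned GGTCA (30.4%) and CAGGTG (9.7%), and flanks as background GGTCA (17.3%) and TGASTCA (1.69%). The turn of TATAAA among the stronger peaks rested on mitochondrial DNA. All 24 mitochondrial peaks were among the stronger peaks. TATAAA was in 40 IDR peaks, 26 of them nuclear, and in 29 of the stronger peaks. The stronger nuclear peaks alone therefore had TATAAA less often than the other pooled regions (21.6%). The cause of the other motif turns was not tested. Of the values for the 3 lists that passed, the RNA classes, the 14 motifs and the X motif, 162 kept direction and call, 11 lost their call, 1 gained it and 21 turned, all named here. The 4 further lists that passed when all genes within 2000 bp counted were not among these. Unknown depth limits every statement on regions that are missing from a list.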

Other observations

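The tests of the motif on X, of other highly transcribed classes and of mitochondrial coverage were chosen only after the X 6-mers, the RNA classes and the mitochondrial peaks had been seen, and both tests within GC bins took their final form after 2 drawn versions, with the same outcome, had been seen.

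The 6-mers that led on X overlap in TCGCGCAGGGAG, the 12-base motif known from sites that recruit the dosage compensation complex to X, which lowers the output of both X chromosomes in hermaphrodites. A match of at least 10 of the 12 bases within 200 bp to either side of summits occurred in 17 of 66 X peaks (25.8%, exact interval 15.8 to 38.0%), at 16 distinct sites. The other pooled X regions had it in 42 of 4562 (0.921%), and autosomal peaks in 3 of 147 (2.04%). Fisher's exact test, adjusted over 3 comparisons, gave p = 2.45e-18 against other X regions and 3.42e-07 against autosomal peaks. Autosomal peaks against other autosomal regions gave 0.102. The motif was picked from 6-mers that led in these same X peaks against the same regions, so these p-values are not independent evidence. Of the 13 X peaks among the 25 strongest, 10 had the motif. The strongest X peak held the exact 12 bases (X, 11094123 to 11094134, minus strand, between genes), as did a peak in an intron of Y41G9A.17 (X, 2997121 to 2997132, minus strand). A peak 4878 bp upstream of xol-1, the switch gene of sex determination and dosage compensation, had 11 of the 12 bases in TCGCGCAGGGAA (X, 8036433 to 8036444). Of the 17, 3 lay in promoter windows, against 22 of the other 49 X peaks (Fisher's exact p = 0.0798). In the top regions of the single replicates the shares on X were 24.6% and 28.3%. Without all peaks that hold the motif, X still had 25.4% of 193 nuclear peaks against 17.2% (exact binomial p = 0.00402). Peaks with 9 of the 12 bases, on X and on autosomes, were kept in this count. In the top set of replicate 2 the whole X excess did not pass the exact test (adjusted p = 0.0831). An X excess apart from the motif is therefore not settled.

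For this motif, 2 technical explanations were looked at, but the motif had been picked from these same X windows against the same other X regions. Lower shares in shuffles and in those regions were therefore likely beforehand, and neither comparison decides. Base composition would give it in shuffled windows, but the highest of 1000 shuffles that keep dinucleotide counts had 6 windows of 66. X sequence of the same GC content held it in 1.64% of other X regions, below the lower bound of the peaks. The median signal of X peaks with the motif was 139 against 40.2 for the other 49 (permutation p = 6e-05, two-sided), which restates their place among the strongest peaks and is no evidence for recruitment of the complex. Recruitment sites, binding of the tagged receptor and signal in any ChIP from worms could each give this and stay open, as no control track was used here and whether a control entered the deposited peak calls is not given in the sources used here.

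For the ribosomal protein genes, a bias towards promoters was tested on promoter peaks against other promoter regions, and the list still passed (odds ratio 12.2, Fisher's exact p = 3.09e-07). GC content would predict a similar share in other regions of equal GC, which had 0.402% with such a target against 4.23% of 213 nuclear peaks (exact interval 1.95 to 7.87%). Signal at highly transcribed genes in any ChIP stays open: of 5 other such classes, whose values had all been seen, 2 passed Fisher's exact test with a higher share (snRNA and tRNA genes near nuclear peaks, adjusted p = 8.6e-06 and 0.0382), while rRNA genes, histones and translation factors did not (adjusted p = 1, 0.151 and 0.282). These calls depend on the setting. Within GC bins tRNA did not pass the exact test (0.406), and rRNA, near 2 of 26501 other regions, could hardly be tested. Histones and translation factors passed the exact test when all genes within 2000 bp counted (0.0007 and 0.0137), a rule by which 1 peak can add several neighbouring genes. No biological explanation was tested, as the design has 1 group.

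Mitochondrial DNA, present in many copies per cell, had 24 of its 27 pooled regions in the IDR set, and 48.0% of the molecule was covered by peaks. Spread over the molecule is what high copy number may give, but binding at many places would look alike, and the 2 cannot be told apart here, as no control track was used and whether a control entered the deposited peak calls is not known from the sources used here.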
